A study of Mus musculus with 120 samples.

How the data were processed

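Polyadenylated RNA was measured by sequencing in 120 libraries of C57BL/6J mouse brain, in 30 groups of 4 biological replicates, each library from cortex, thalamus or hypothalamus. Per the labels' protocols, mice received adeno-associated virus by retro-orbital injection 3 weeks before dissection, RNA was isolated with the RNAprep Pure Tissue Kit (TIANGEN), and the library kit was NEBNext Ultra II DNA. Per the submitters' processing notes, the tools were CASAVA 1.9, STAR 2.6.1a, featureCounts (no version given) and edgeR 3.28.1, and the genome build was GRCm38. The annotation release, the filters, the handling of reads that map to several places and the strand setting of the counting were not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

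The authors deposited 1 table per library with 49585 gene rows. Per the file headers, the values are RPKM in the 36 libraries of wild-type mice that received mCherry, HDAC4CA or CREB, and FPKM in the other 84 libraries, which comprise all Sleepy mice and the wild-type mice that received eGFP. Both deposited units divide reads by gene length and by library size, so a level is relative to the rest of the same library. Each comparison of 2 groups lay within 1 set, and levels were not compared across sets. Comparing a transgene effect between genotypes therefore set a difference in RPKM against one in FPKM. The control vectors differed as well (mCherry in wild-type, eGFP in Sleepy mice).

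The low values of a library were whole multiples of 1 step once multiplied by exon length, taken from the GENCODE M21 annotation of GRCm38. Of the values worth up to 20 reads, 94.3% to 95.7% per library lay within 0.1 of a whole read. This gave the depth of each library, 13.52 to 28.16 M reads assigned to genes with a median of 18.7 M, and the reads of each gene. The 26 symbols a spreadsheet had turned into dates were left out, and 93 repeated symbols kept 1 row each. Of the 49466 genes kept, 95.2% had an exon length.

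Values were scaled by the trimmed mean of M values, computed on the recovered reads with 0.3 of the log ratios and 0.05 of the mean levels trimmed at each end, and moved to log2(value + 0.1). All fold changes are on that scale, which understates the change of low genes. Genes with a mean of at least 10 recovered reads over the libraries compared were tested (without an exon length, a mean value of at least 1). Tests were made with limma 3.58.1 in R 4.3.3, with an intensity trend, robust variances and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Each comparison used only the libraries of its groups in 1 region. Every adjusted p of a gene is from this limma fit. The comparisons, alternatives, gene lists and the naming rule were fixed before the data were examined, on the assumption that the files would hold counts. Because they hold RPKM and FPKM, the planned edgeR test was not run, and limma on log values was used instead. Counts of called genes without rescaling were seen before the scaled fit was made, and the former are given where the count moved by more than 1.5 times or the split of higher and lower genes shifted.

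Comparisons followed the series' design text: HDAC4CA or CREB against mCherry in wild-type mice, Sleepy against wild-type mice at both times, and HDAC4CA or CREB against eGFP in Sleepy mice. The time comparison in wild-type mice and 3 interactions (genotype by time, HDAC4CA by genotype, CREB by genotype) were added. Differences in effect between regions were not tested. Lists of pathway genes and of markers of cell types and neighbouring tissue (38 lists) were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move on balance in 1 direction. Adjusted p-values of lists were taken over the lists of 1 comparison.

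Named genes were, for each comparison and region, the 3 with the largest rise and the 3 with the largest fall among called genes with a mean of at least 2 CPM and all 4 libraries of one group beyond all 4 of the other. Symbols of the form Gm with digits, symbols ending in Rik, pseudogenes and unnamed identifiers were skipped. Hdac4, Creb1 and Sik3 were named everywhere. Of each list described (at least 3 called members), up to 4 members with the smallest adjusted p were named, and for the time comparison the core clock genes instead. Some genes that this rule names are not reported here.

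Wild-type cortex held libraries of 2 kinds, parted by the mean log2 level of ribosomal protein genes at 2.5. Replicate numbers in the labels were checked for pairing by correlating the deviations of same-numbered libraries from their group means. In 2 of 24 comparisons, HDAC4CA and CREB against mCherry in wild-type cortex, all 4 correlations were above 0.1 (0.13 to 0.65 and 0.13 to 0.71). There the number 4 carries the library kind in all groups, and no label names a shared animal or batch. Over 180 pairs of replicates the chi-square per gene was 2.03 to 42.37, so no library was counted as a copy of another.

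The fit was tested on simulated data with 200 changed genes. For HDAC4CA against mCherry in wild-type cortex (15535 genes), 29.9% of the genes changed 1.5-fold, 79.1% of those changed 2-fold and 90.9% of those changed 4-fold were called, and 9.5% of all calls were false. For Sleepy against wild-type thalamus at ZT12.5 (16545 genes) the shares were 32.8%, 80.6% and 93.9%, with 2.8% false calls. Alternatives fixed beforehand were median-of-ratios scaling, no filter, a replicate block and each library left out in turn. No rescaling, a pseudocount of 1, voom on recovered reads, a term for library kind, cortex without the libraries of the low kind and a choroid plexus score as a covariate were chosen after the files had been seen. Other splits of the same libraries were refitted, all 35 for 2 groups of 4 and 100 drawn for an interaction, and in wild-type cortex the 8 that part all pairs of the same number, and pairs of comparisons were set against 200 simulations. Other tools were data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.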

Results

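RNA of mouse cortex, thalamus and hypothalamus was profiled in 30 groups of 4 libraries each. Mice were wild type or Sleepy, which carry 1 copy of an allele of Sik3 (salt-inducible kinase 3) without exon 13, written Sik3E13Δ/+. A virus delivered HDAC4CA, a form of the class IIa histone deacetylase HDAC4, or the transcription factor CREB, or a fluorescent protein as control (mCherry or eGFP). Tissue was taken at ZT12.5, just after lights off, or at ZT0.5, just after lights on. Wild-type mice with mCherry, HDAC4CA or CREB at ZT12.5 made up 36 libraries (RPKM, 14.84 to 28.16 M reads assigned to genes). The other groups made up 84 (FPKM, 13.52 to 24.52 M).

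Hdac4 and Creb1, the endogenous genes of the delivered proteins, were read first in every group. Hdac4 rose in all 9 comparisons of HDAC4CA with its control. In wild-type thalamus it stood at 7.36 ± 0.264 RPKM (SD, n = 4) with HDAC4CA and 2.65 ± 0.13 with mCherry, a 2.84-fold rise (adjusted p = 2.6e-06). Wild-type cortex and hypothalamus showed 1.80-fold (adjusted p = 0.00091) and 1.73-fold (adjusted p = 0.001) rises. In Sleepy mice at ZT12.5 Hdac4 rose 3.67-fold in thalamus (9.59 ± 1.55 against 2.57 ± 0.198 FPKM), 1.84-fold in cortex and 2.03-fold in hypothalamus. At ZT0.5 the rises were 3.00-fold, 1.69-fold and 2.22-fold in thalamus, cortex and hypothalamus. Creb1 rose with CREB 3.08-fold in wild-type thalamus (12.1 ± 1.81 against 3.84 ± 0.113 RPKM) and 1.87-fold in cortex. Wild-type hypothalamus gave a log2 difference of 0.48 ± 0.06 (SE), which missed the threshold (adjusted p = 0.13). In Sleepy mice Creb1 rose 7.11-fold in thalamus (17.1 ± 2.0 against 2.17 ± 0.0782 FPKM), 3.13-fold in cortex and 2.15-fold in hypothalamus. Reads of a construct add to the endogenous gene only as far as they map there, so these folds do not separate both sources. Sik3 was called in none of the 8 kinds of comparison in any region. In Sleepy thalamus at ZT12.5 it stood at 12.4 ± 0.666 FPKM against 13.6 ± 0.444 in wild type. A level summed over the gene does not show the absence of 1 exon.

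**Figure D1:**
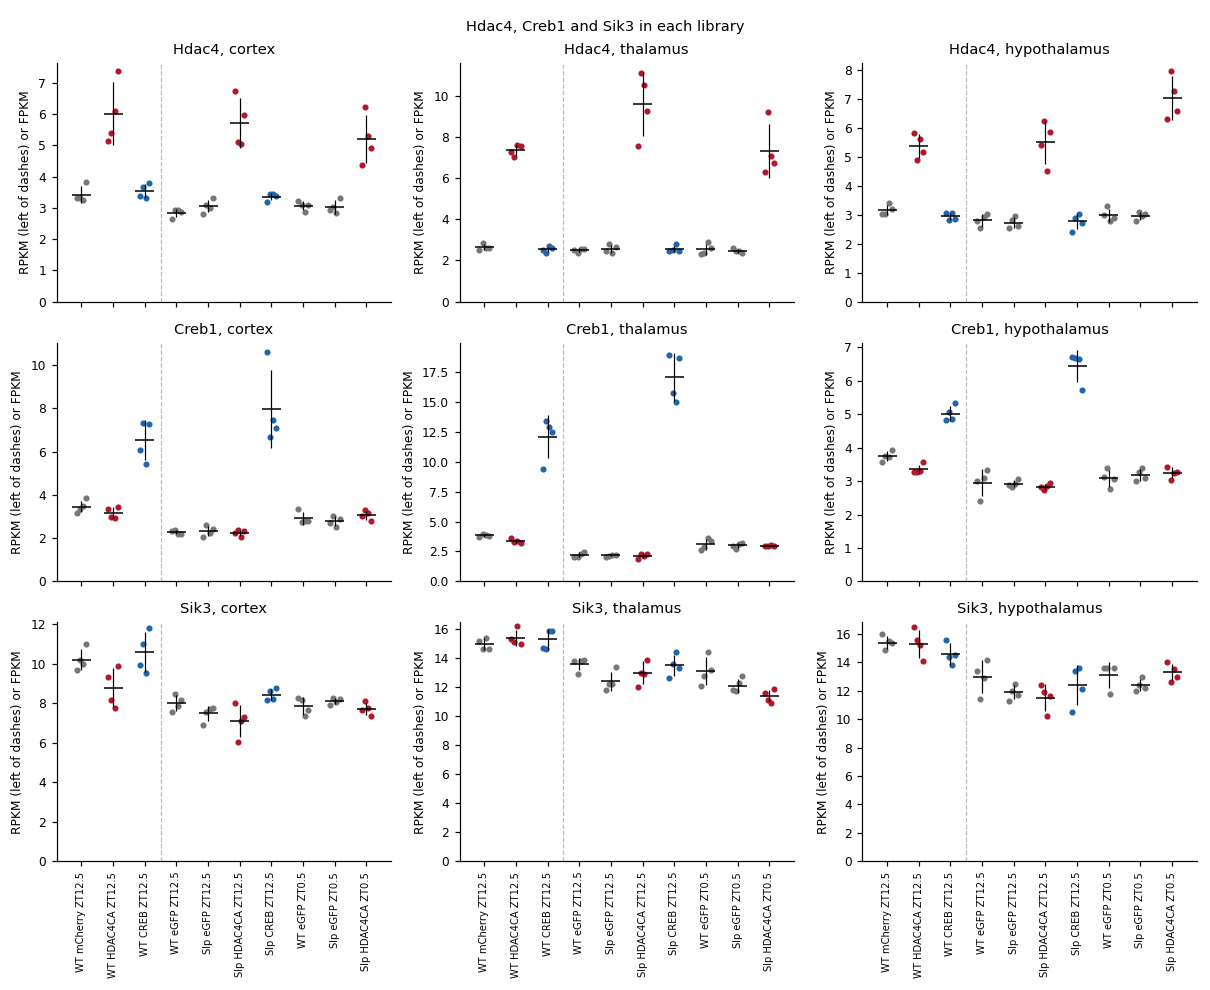
Levels of Hdac4, Creb1 and Sik3 per library in each group and region, in RPKM left of the dashed line and FPKM right of it, with red dots for HDAC4CA groups, blue dots for CREB groups and grey dots for all others. Horizontal lines are means and bars are SDs of 4 libraries. In wild-type thalamus Hdac4 averaged 7.36 RPKM with HDAC4CA against 2.65 with mCherry.

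In wild-type cortex, HDAC4CA was compared with mCherry at ZT12.5. Serpina3n, a serine protease inhibitor of reactive astrocytes, rose from 2.69 ± 0.519 to 9.14 ± 2.27 RPKM (SD, n = 4; log2 fold change 1.79 ± 0.19 SE, adjusted p = 0.0017). Slc6a5, the glycine transporter of glycinergic neurons, rose by 2.51 ± 0.38 from near 0, and Blnk, an adaptor of B-cell receptor signalling, by 1.81 ± 0.27. Plk5, of the polo-like kinase family, fell from 2.69 ± 0.245 to 0.416 ± 0.263 RPKM (log2 −2.48 ± 0.28). Frzb, a secreted Wnt antagonist, changed by −1.87 ± 0.18 and Cartpt, the precursor of the peptide CART, by −1.51 ± 0.33. Reactive astrocyte genes rose as a group: 5 of 9 were called up, none down and 4 were not called, or 7 of 9 with p adjusted over the list alone (hereafter "over the list alone"). Gfap, the astrocyte intermediate filament, rose by 1.22 ± 0.15, the hyaluronan receptor Cd44 by 0.87 ± 0.12 and complement C4b by 0.93 ± 0.16. The camera adjusted p was 3.3e-05 (adjusted p = 0.1 with an estimated correlation). Myelin genes had a median of −0.22 in this comparison with 0 of 12 called (5 lower over the list alone; camera adjusted p = 0.002, adjusted p = 0.81 with an estimated correlation). Of 19 genes of the circadian clock and its output, 3 fell and 16 were not called (8 fell over the list alone; camera adjusted p = 0.002, adjusted p = 0.31 with an estimated correlation). These were Npas2 (−0.36 ± 0.08), Cry2 (−0.19 ± 0.05) and Tef (−0.27 ± 0.07). With the replicate number as a block Cartpt and Cry2 lost their calls (adjusted p = 0.091 and 0.067).

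In all, 1087 of 15891 genes were called in wild-type cortex with HDAC4CA, 579 higher and 508 lower. The values without rescaling gave 160 higher and 422 lower. In replicate 4 of each wild-type cortex group, ribosomal protein genes averaged 1.62 to 1.64 on the log2 scale against 3.56 to 3.77 in replicates 1 to 3, and Gapdh, a glycolytic enzyme, 5.85 to 6.47 against 51.4 to 59.7 RPKM. Without the replicates of this low kind 512 genes were called (291 higher, 221 lower), and a single library per group of the low kind gave no test. With a term for library kind, chosen after the data had been seen, 1414 were called (799 higher, 615 lower). Each library left out in turn moved the count by more than 1.5 times: to 1970, 653, 719 and 702 without HDAC4CA libraries 1 to 4, and to 543, 535, 505 and 610 without mCherry libraries 1 to 4.

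Wild-type thalamus with HDAC4CA showed a rise of Gal, the precursor of galanin, from 3.29 ± 0.663 to 11 ± 0.867 RPKM (SD, n = 4; log2 1.80 ± 0.12 SE, adjusted p = 5.6e-05). The immediate early genes Egr4 (2.17 ± 0.44) and Fosb (1.74 ± 0.39) also rose. Cck, the precursor of cholecystokinin, fell from 33.1 ± 0.561 to 11.4 ± 1.33 RPKM (log2 −1.47 ± 0.08, adjusted p = 1e-05). Gpr4, a proton-sensing receptor, and the ligand Wnt9a changed by −1.43 ± 0.12 and −1.42 ± 0.11. Among GABA-A receptor subunits 5 of 12 fell and 1 rose: Gabra4 by −1.1 ± 0.06, Gabrb2 by −0.44 ± 0.05 and Gabrb1 by −0.35 ± 0.05 among those that fell (6 fell and 1 rose over the list alone). The list's camera adjusted p was 0.0049 (adjusted p = 0.87 with an estimated correlation). Cholesterol synthesis genes rose: 7 of 15 were called, none fell, and 11 rose over the list alone, with Cyp51 at 0.34 ± 0.04, Insig1 at 0.30 ± 0.06 and the regulator Srebf2 at 0.24 ± 0.04 (camera adjusted p = 5.7e-06, adjusted p = 0.87 with an estimated correlation). Of 13 microglia markers 4 rose and none fell (6 over the list alone), the complement genes C1qb at 0.57 ± 0.07 and C1qa at 0.60 ± 0.12 among them, with a camera adjusted p of 0.00027 (adjusted p = 0.87 with an estimated correlation). Reactive astrocyte genes rose in 4 of 10 cases, also over the list alone, with Serpina3n at 1.26 ± 0.25 and Gfap at 0.56 ± 0.11 (camera adjusted p = 0.0032, adjusted p = 0.87 with an estimated correlation). Of 20 genes of presynaptic release 4 rose and 2 fell (6 and 2 over the list alone). The vesicle proteins Vamp2 and Syp rose by 0.31 ± 0.05 and 0.26 ± 0.05, and Bsn, of the active zone, changed by −0.27 ± 0.06 (camera adjusted p = 0.02, adjusted p = 0.97 with an estimated correlation).

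The count in wild-type thalamus was 1260 of 16787 genes, 746 higher and 514 lower, and without rescaling 359 higher and 868 lower. Choroid plexus markers, of the tissue that lines the ventricles, had a median log2 difference of −1.93 there with 0 of 11 called. Ttr, the most abundant of them, ranged from 4.28 to 1490 RPKM over the 4 HDAC4CA libraries and from 23.8 to 1690 over the mCherry libraries. Without HDAC4CA library 3 the count was 760, without mCherry library 2 it was 770 and without mCherry library 4 it was 734.

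Wild-type hypothalamus with HDAC4CA showed 23 called genes of 16434, 17 higher and 6 lower. Agrp, the precursor of agouti-related peptide, rose from 1.52 ± 0.142 to 4.94 ± 0.434 RPKM (SD, n = 4; log2 1.68 ± 0.09 SE, adjusted p = 2.2e-05), and Sst, the precursor of somatostatin, from 66.6 ± 2.74 to 127 ± 13.8 (log2 0.97 ± 0.08). The kinase gene Ptk2b rose by 0.97 ± 0.13. Falls were led by Nrep (−0.61 ± 0.08), the purinergic receptor P2ry1 (−0.45 ± 0.07) and Kcnj9, a subunit of G protein-gated potassium channels (−0.44 ± 0.06). Of 21 neuropeptide genes of sleep and wake, 2 rose, none fell and 19 were not called, or 9 rose and 1 fell over the list alone. The list's camera adjusted p was 5.5e-07, and adjusted p = 0.046 with an estimated correlation. Without rescaling 13 genes were higher and 8 lower, and voom on recovered reads called 86. Each library left out moved the count: to 193, 12, 10 and 13 without HDAC4CA libraries 1 to 4, and to 10, 8, 12 and 12 without mCherry libraries 1 to 4.

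CREB in wild-type mice was compared with mCherry at ZT12.5. In thalamus Cacna1s, a calcium channel subunit known from skeletal muscle, rose from 0.267 ± 0.0265 to 1.54 ± 0.384 RPKM (SD, n = 4; log2 2.14 ± 0.17 SE, adjusted p = 0.00066) and the keratin gene Krt20 by 1.95 ± 0.20. Olfr539, an olfactory receptor gene, changed by −1.14 ± 0.20 and was low throughout (0.0752 against 0.297 RPKM), and Abhd12b and Impa2 changed by −0.94 ± 0.19 and −0.68 ± 0.12. Nuclear-encoded subunits of oxidative phosphorylation rose in 4 of 74 cases and fell in none, or 13 over the list alone. The members of complex I Ndufa7 (0.29 ± 0.06), Ndufa2 (0.17 ± 0.03), Ndufb9 (0.14 ± 0.03) and Ndufv3 (0.24 ± 0.06) were those called, with a camera adjusted p of 6.6e-08 (adjusted p = 0.52 with an estimated correlation). Of 18 ion channel genes from models of sleep 2 rose and 3 fell (2 and 6 over the list alone; camera adjusted p = 0.017, adjusted p = 0.74 with an estimated correlation). The pacemaker channel Hcn2 and the T-type calcium channel Cacna1g rose by 0.21 ± 0.03 and 0.22 ± 0.04, while the potassium channel genes Kcnc2 and Kcnab2 changed by −0.27 ± 0.06 and −0.20 ± 0.04. In all 560 of 16888 genes were called in thalamus, 342 higher and 218 lower. The count fell without CREB libraries 2, 3 and 4 (192, 248 and 258) and without mCherry libraries 1, 2 and 4 (370, 317 and 216).

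In wild-type cortex with CREB, 8 of 16065 genes were called, 6 higher and 2 lower. Beside Creb1 these included Crhbp, which binds corticotropin-releasing hormone (0.54 ± 0.06 SE), and Ptprn, a protein of secretory granules (0.19 ± 0.02). With the replicate number as a block, which is paired here by library kind, 1 gene was called, Crhbp and Ptprn had adjusted p = 0.1 and 0.12. Without the replicates of the low kind 5 genes were called, and with a term for library kind 12. Each library left out moved the count, to 1, 1, 1 and 3 without CREB libraries 1 to 4 and to 1, 1, 1 and 2 without mCherry libraries 1 to 4. Interferon response genes had a camera adjusted p of 0.08 without the block (adjusted p = 0.61 with an estimated correlation) and 0.043 with it (adjusted p = 0.68 with an estimated correlation). In wild-type hypothalamus with CREB, limma called 0 of 16550 genes, 655 had an unadjusted p under 0.05 (828 by chance), and voom called 1.

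Sleepy mice were compared with wild-type mice, both with eGFP, to find what the Sik3 allele changes. In thalamus at ZT0.5 6 of 16719 genes were called, all lower. Irs4, an insulin receptor substrate, stood at 0.708 ± 0.0793 against 1.76 ± 0.281 FPKM (SD, n = 4; log2 −1.15 ± 0.14 SE, adjusted p = 0.039). Peg10, an imprinted gene of retroviral origin, and Baiap3, of the Munc13 family of exocytosis proteins, fell by 0.84 ± 0.09 and 0.60 ± 0.06 on the log2 scale (adjusted p = 0.02 and 0.013). The other 3, chosen after their values were seen, were Hap1, Tac2 and Gad2 (log2 −0.55, −0.51 and −0.37), the last 2 a tachykinin precursor and an enzyme of GABA synthesis. Hap1 and Tac2 stand on the list of habenula markers, where 2 of 7 fell, also over the list alone, with a median of 0.05 (camera adjusted p = 0.076, adjusted p = 0.61 with an estimated correlation). Markers of hypothalamus were lower in the same thalamus libraries, with a median log2 difference of −0.61 over 11 genes, 0 called and 3 lower over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.2 with an estimated correlation). Neuropeptide genes had a median of −0.44 (camera adjusted p = 1.4e-07, adjusted p = 0.2 with an estimated correlation). At the same time, voom called 47 genes, 3 higher and 44 lower. The count was 3 without Sleepy library 2, 0 without Sleepy library 3 or 4, 1 without wild-type library 1 or 2 and 0 without wild-type library 4.

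In the other 5 comparisons of Sleepy with wild-type tissue limma called 0 genes. At ZT0.5, 966 genes in cortex and 769 in hypothalamus had an unadjusted p under 0.05 (799 and 858 by chance), and voom called 3 and 0. At ZT12.5 these counts were 1083 in cortex, 1337 in thalamus and 1455 in hypothalamus (822, 847 and 867 by chance), and voom called 3, 2 and 3. Without Sleepy library 2 limma called 1 gene in thalamus at ZT12.5. Myelin genes of thalamus at ZT12.5 had a median log2 difference of −0.31 with 0 of 12 called, or 12 of 12 lower over the list alone (camera adjusted p = 1.5e-20, adjusted p = 0.2 with an estimated correlation). At ZT0.5 the same genes had a median of 0.10 (camera adjusted p = 0.00056, adjusted p = 0.44 with an estimated correlation). Choroid plexus markers had a median of 1.0 in the ZT12.5 thalamus comparison.

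**Figure D2:**
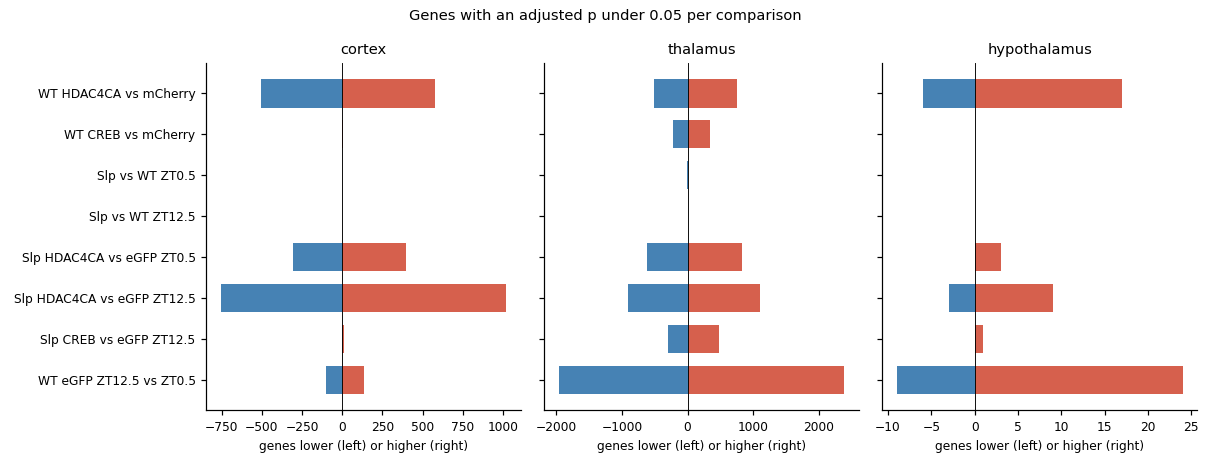
Numbers of genes called higher and lower (adjusted p under 0.05, limma) in each comparison, with 1 panel per region and a different scale of the horizontal axis in each. The count of Sleepy against wild-type tissue was 6 in thalamus at ZT0.5 and 0 in the other 5 cases, while HDAC4CA in Sleepy thalamus at ZT12.5 gave 2020.

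HDAC4CA in Sleepy mice was compared with eGFP at both times, to see how the transgene acts on the Sik3E13Δ/+ background. In cortex at ZT12.5 Nptx2, a synaptic pentraxin, rose from 7.38 ± 0.945 to 38.0 ± 7.92 FPKM (SD, n = 4; log2 2.34 ± 0.11 SE, adjusted p = 7.9e-06). Aspg rose by 2.04 ± 0.24 and Serpina3n by 2.02 ± 0.28. Plk5 changed by −2.42 ± 0.16, Npas4, an activity-dependent transcription factor, by −2.22 ± 0.28 and Frzb by −2.0 ± 0.22. Cholesterol synthesis genes rose in 12 of 15 cases and fell in none, or 13 over the list alone. Hmgcs1 rose from 35.2 ± 0.812 to 53.2 ± 1.92 FPKM (log2 0.60 ± 0.04), Insig1 by 0.56 ± 0.08 and Sqle by 0.54 ± 0.08, with a camera adjusted p of 7.8e-12 and adjusted p = 0.016 with an estimated correlation. Reactive astrocyte genes rose in 5 of 9 cases, also over the list alone, with Gfap at 1.71 ± 0.14 and C4b at 1.27 ± 0.13 (camera adjusted p = 0.00015, adjusted p = 0.58 with an estimated correlation). Interferon response genes rose in 4 of 17 cases (9 over the list alone), the regulator Irf7 by 0.98 ± 0.24 and Ifit1 by 0.81 ± 0.22 (camera adjusted p = 0.00032, adjusted p = 0.67 with an estimated correlation).

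GABA-A receptor subunits fell in 4 of 12 cases and rose in 1 in the same cortex comparison (7 and 1 over the list alone): Gabrd by −1.07 ± 0.10 and Gabrb2 by −0.27 ± 0.05 (camera adjusted p = 0.016, adjusted p = 0.67 with an estimated correlation). Of 20 immediate early genes 3 fell and 1 rose (8 and 3 over the list alone). Npas4, Btg2 (−1.01 ± 0.21) and Nr4a2 (−0.49 ± 0.11) fell and Ier5 rose by 0.53 ± 0.11 (camera adjusted p = 0.032, adjusted p = 0.72 with an estimated correlation). Of 84 ribosomal protein genes, whose reads can be shared with pseudogenes, 6 fell and 1 rose, also over the list alone, Rps29 by −0.26 ± 0.05 and Rps2 by 0.19 ± 0.04 among them (camera adjusted p = 0.004, adjusted p = 0.67 with an estimated correlation). Cortical markers fell in 3 of 9 cases and rose in 1 (4 and 1 over the list alone), Lamp5 by −1.1 ± 0.08 and Cux2 by 0.37 ± 0.08 (camera adjusted p = 0.024, adjusted p = 0.67 with an estimated correlation). The whole count was 1779 of 16347 genes, 1021 higher and 758 lower. Blood cell genes had a median of −1.0 in these libraries with 0 of 5 called.

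At ZT0.5 Sleepy cortex with HDAC4CA gave 704 called genes of 15912, 395 higher and 309 lower. Aspg (1.68 ± 0.26 SE), Blnk (1.49 ± 0.17) and Serpina3n (1.26 ± 0.25) rose most, and Plk5 (−2.20 ± 0.41), Frzb (−1.40 ± 0.17) and Ankrd63 (−1.33 ± 0.14) fell most. Cholesterol synthesis genes rose in 7 of 15 cases (13 over the list alone), Insig1 by 0.51 ± 0.09 and Hmgcs1 by 0.45 ± 0.08 (camera adjusted p = 9.1e-10, adjusted p = 0.37 with an estimated correlation). Clock and clock output genes fell in 7 of 18 cases and rose in 1 (10 and 2 over the list alone), with Dbp from 6.75 ± 0.868 to 3.47 ± 0.603 FPKM (log2 −0.94 ± 0.14) and Ciart at −0.70 ± 0.14 (camera adjusted p = 0.001, adjusted p = 0.37 with an estimated correlation). Subunits of GABA-A receptors fell in 5 of 12 cases, also over the list alone, Gabrd by −1.08 ± 0.15 and Gabra4 by −0.29 ± 0.06 (camera adjusted p = 0.023, adjusted p = 0.37 with an estimated correlation). Chaperone genes rose in 3 of 19 cases (6 over the list alone): Hsph1 by 0.42 ± 0.05, Calr by 0.30 ± 0.06 and Hspa8 by 0.20 ± 0.04 (camera adjusted p = 0.00012, adjusted p = 0.5 with an estimated correlation). Markers of excitatory neurons rose in 3 of 9 cases, also over the list alone, Neurod2 by 0.58 ± 0.07 and the glutamate transporter Slc17a7 by 0.50 ± 0.08 (camera adjusted p = 0.04, adjusted p = 0.6 with an estimated correlation). Blood cell genes fell in 3 of 5 cases (5 over the list alone), Hbb-bt by −0.91 ± 0.15 and Hba-a1 by −0.81 ± 0.17, which share reads with near-identical copies (camera adjusted p = 3.2e-05, adjusted p = 0.37 with an estimated correlation). The count was 355, 401 and 416 without HDAC4CA libraries 2, 3 and 4, and 378, 311 and 365 without eGFP libraries 1, 2 and 3.

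In Sleepy thalamus at ZT0.5 HDAC4CA raised Gal from 1.17 ± 0.462 to 10 ± 2.75 FPKM (SD, n = 4; log2 3.10 ± 0.28 SE, adjusted p = 0.00044), Nfam1, an immunoreceptor, by 1.93 ± 0.22 and Crispld2 by 1.85 ± 0.17. Car4, a carbonic anhydrase, changed by −1.69 ± 0.12, Gpr4 by −1.65 ± 0.10 and Cck by −1.62 ± 0.13. Cholesterol synthesis genes rose in 9 of 15 cases (10 over the list alone), Sqle by 0.46 ± 0.06 and Fdft1 by 0.44 ± 0.06 (camera adjusted p = 1e-08, adjusted p = 0.45 with an estimated correlation). Genes of presynaptic release rose in 6 and fell in 2 of 20 cases (10 and 2 over the list alone), with Vamp2 at 0.40 ± 0.04 and Bsn at −0.49 ± 0.07 (camera adjusted p = 0.0015, adjusted p = 0.45 with an estimated correlation). Myelin genes fell in 4 of 12 cases (9 over the list alone), Mog by −0.44 ± 0.08 and Cnp by −0.35 ± 0.06, with a camera adjusted p of 7.1e-06 (adjusted p = 0.45 with an estimated correlation). Astrocyte markers fell in 4 of 12 cases (6 over the list alone), the gap junction gene Gja1 by −0.28 ± 0.04 and the water channel Aqp4 by −0.25 ± 0.07 (camera adjusted p = 0.00058, adjusted p = 0.45 with an estimated correlation). Chaperone genes rose in 4 of 19 cases (8 over the list alone), Calr by 0.35 ± 0.08 and Hspa8 by 0.25 ± 0.05 (camera adjusted p = 0.001, adjusted p = 0.52 with an estimated correlation). Ribosomal protein genes fell in 3 of 84 cases (0 over the list alone), Rps14 by −0.23 ± 0.06 among them (camera adjusted p = 2.5e-10, adjusted p = 0.45 with an estimated correlation). In all 1436 of 16733 genes were called, 823 higher and 613 lower, and without rescaling 476 higher and 1177 lower. Blood cell genes had a median of −1.01 in these libraries. Without HDAC4CA library 3 the count was 938.

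In Sleepy thalamus at ZT12.5 the choroid plexus gene Ttr, the precursor of transthyretin, fell from 961 ± 445 to 8.27 ± 2.66 FPKM with HDAC4CA (SD, n = 4; log2 −6.75 ± 0.30 SE, adjusted p = 4.7e-06). The channel genes Kcne2 and Kcnj13 changed by −4.75 ± 0.30 and −4.74 ± 0.29, Kl (klotho) by −4.57 ± 0.27 and Sostdc1 by −3.91 ± 0.21. In all 9 of 11 choroid plexus and ependyma markers fell, or 10 over the list alone, with a median of −4.14 (camera adjusted p = 2.7e-16, adjusted p = 0.25 with an estimated correlation). Blood cell genes fell in 5 of 5 cases, also over the list alone, Hbb-bs by −1.16 ± 0.27 and Hba-a1 by −1.13 ± 0.26, copies that share reads (camera adjusted p = 0.00069, adjusted p = 0.59 with an estimated correlation). With a choroid plexus score as a covariate, chosen after the data had been seen, 0 genes were called by limma against 2020 without it, and the score and the transgene could not be separated in this comparison. With the score 1121 genes had an unadjusted p under 0.05, and without it 4393.

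**Figure D3:**
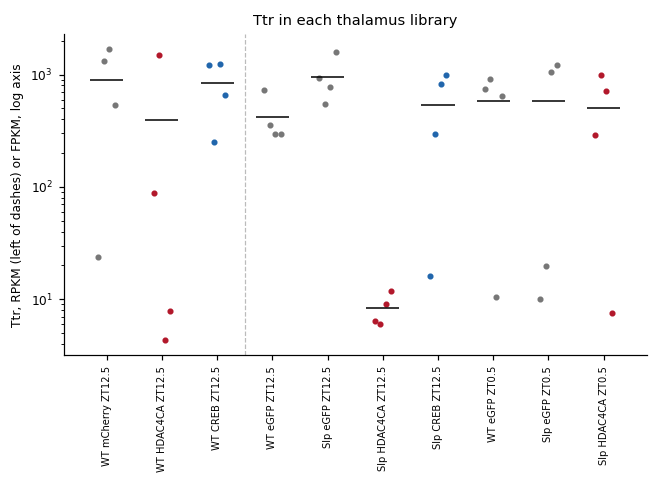
Ttr level of each thalamus library in RPKM or FPKM on a log axis, by group, with a horizontal line at the mean of 4 libraries and no error bar. The HDAC4CA libraries of Sleepy mice at ZT12.5 lie between 5.96 and 11.7 FPKM, and the libraries of the same region without HDAC4CA in the FPKM files between 10.1 and 1583.

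Beside these markers, Gal rose from 2.23 ± 1.38 to 10 ± 1.15 FPKM in Sleepy thalamus at ZT12.5 (SD, n = 4; log2 2.39 ± 0.42 SE), the early gene Egr3 by 2.02 ± 0.32 and Nfam1 by 1.94 ± 0.20. Cholesterol synthesis genes rose in 9 of 15 cases (11 over the list alone), Fdft1 by 0.44 ± 0.05 and Insig1 by 0.41 ± 0.06 (camera adjusted p = 6.7e-08, adjusted p = 0.067 with an estimated correlation). Presynaptic release genes rose in 9 of 20 cases and fell in 1 (11 and 3 over the list alone), Vamp2 by 0.42 ± 0.04, Syp by 0.35 ± 0.05 and the synapsin gene Syn1 by 0.26 ± 0.04 (camera adjusted p = 0.00061, adjusted p = 0.53 with an estimated correlation). Of the GABA-A receptor subunits 4 of 12 fell, or 5 with 1 rise over the list alone. Gabra4 fell from 17.9 ± 1.85 to 7.50 ± 1.38 FPKM (log2 −1.22 ± 0.10) and Gabrb1 by −0.55 ± 0.07 (camera adjusted p = 0.021, adjusted p = 0.61 with an estimated correlation). Ribosomal protein genes fell in 7 of 84 cases (2 over the list alone), Rpl8 by −0.21 ± 0.04 among them (camera adjusted p = 3.2e-07, adjusted p = 0.067 with an estimated correlation). Chaperone genes fell in 3 and rose in 1 of 19 cases (5 and 1 over the list alone), Pdia4 by −0.39 ± 0.08 and Hspa8 by 0.18 ± 0.03 (camera adjusted p = 0.042, adjusted p = 0.67 with an estimated correlation). In all 2020 of 16835 genes were called, 1106 higher and 914 lower, and without rescaling 418 higher and 663 lower. The count was 1324 without HDAC4CA library 1, 1313 without HDAC4CA library 3 and 1287 without eGFP library 1.

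**Figure D4:**
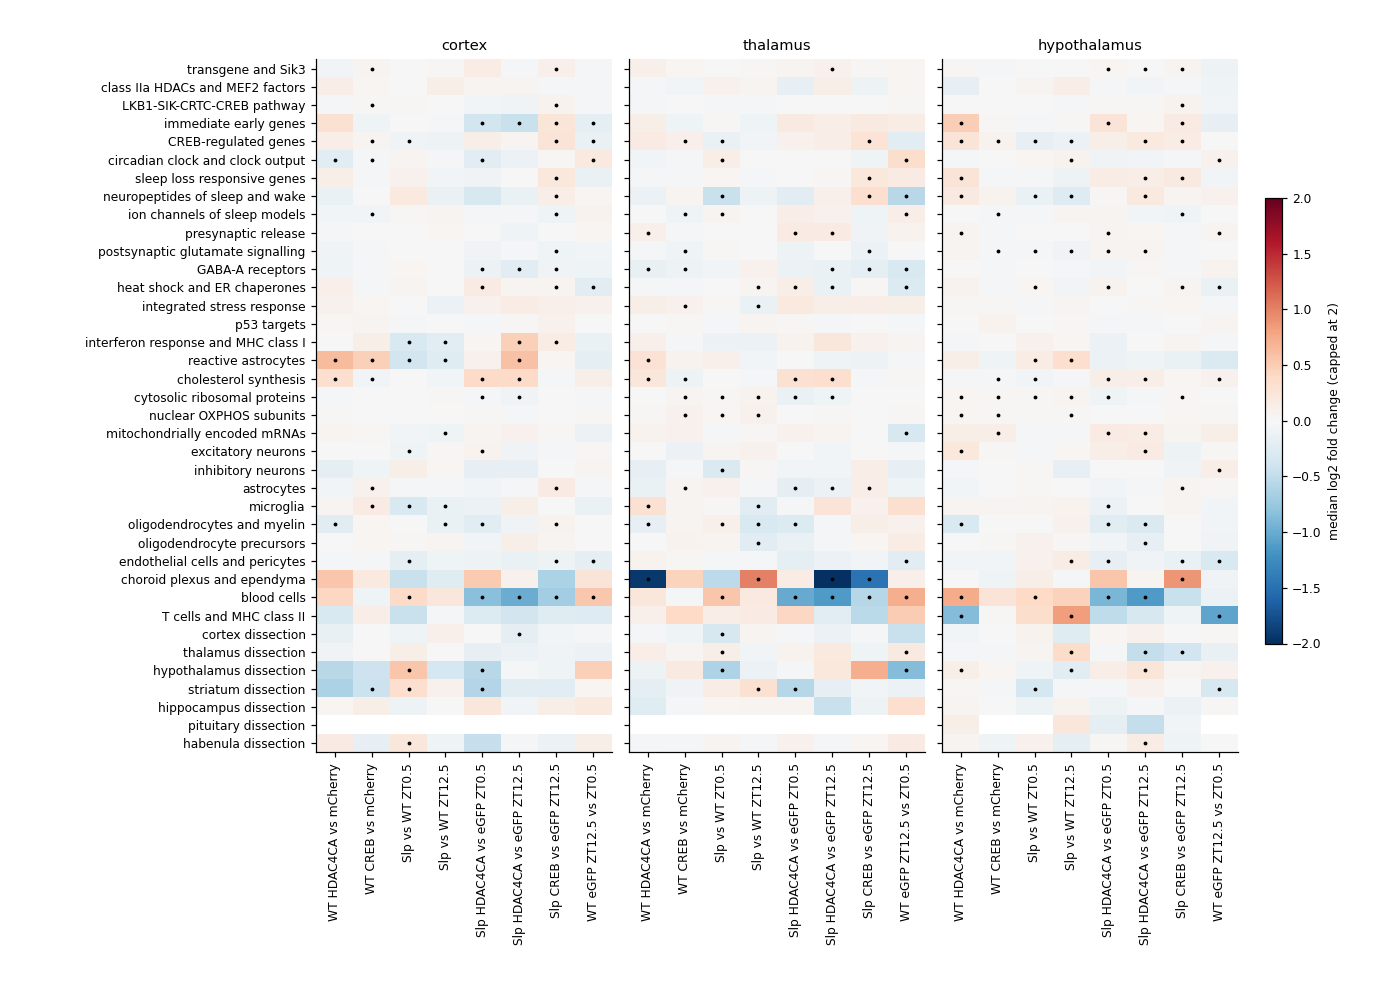
Median log2 fold change of gene lists (vertical axis) in each comparison (horizontal axis), with 1 panel per region, in colour capped at 2 in size, with a dot where the camera adjusted p was under 0.05 at the preset correlation and blank cells where a list was not tested. Cholesterol synthesis genes have a median of 0.38 in Sleepy cortex and 0.33 in Sleepy thalamus with HDAC4CA at ZT12.5.

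Sleepy hypothalamus with HDAC4CA gave 12 called genes of 17343 at ZT12.5, 9 higher and 3 lower. Egr3 rose from 0.573 ± 0.262 to 5.55 ± 1.99 FPKM (SD, n = 4; log2 3.11 ± 0.33 SE, adjusted p = 0.031) and Npy, the precursor of neuropeptide Y, from 8.05 ± 0.715 to 19.1 ± 3.95 (log2 1.26 ± 0.15). Chrna6, a nicotinic receptor subunit (−1.15 ± 0.16), Nrep (−0.66 ± 0.09) and Gpr17, a receptor of the oligodendrocyte lineage (−0.51 ± 0.06), fell. At ZT0.5 the 3 genes called of 17104 were Hdac4, Gal (from 12.3 ± 1.06 to 18.9 ± 1.76 FPKM, log2 0.55 ± 0.06) and Gm26720 (2.01), the last chosen after its values were seen. Blood cell genes had medians of −1.13 at ZT12.5 and −0.91 at ZT0.5, with 0 of 5 called at either time. At ZT12.5 voom called 73 genes, and the count was 3, 5, 5 and 2 without HDAC4CA libraries 1 to 4 and 3, 4, 3 and 3 without eGFP libraries 1 to 4.

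CREB in Sleepy mice was compared with eGFP at ZT12.5. In thalamus Cacna1s rose from 0.245 ± 0.0446 to 3.13 ± 1.1 FPKM (SD, n = 4; log2 3.10 ± 0.24 SE, adjusted p = 0.00028) and Cenpa, the centromeric histone H3 variant, from 0.0641 ± 0.0177 to 1.03 ± 0.313 (log2 2.69 ± 0.22). Abhd12b (−1.34 ± 0.28), Dusp27 (−1.18 ± 0.19) and Strip2 (−1.11 ± 0.24) fell. Genes known to be regulated by CREB rose in 3 of 21 cases and fell in none (4 over the list alone). Crem, of the CREB family, rose by 0.85 ± 0.12, the kinase Sik1 by 0.77 ± 0.09 and the neuropeptide precursor Vgf by 0.45 ± 0.11 (camera adjusted p = 0.0029, adjusted p = 0.51 with an estimated correlation). Genes that respond to sleep loss rose in 5 of 18 cases (8 over the list alone). The heat shock genes Hspa1b and Hspa1a, which share reads, rose by 1.36 ± 0.20 and 1.13 ± 0.18, and the cold-inducible Rbm3 by 0.36 ± 0.07 (camera adjusted p = 0.0038, adjusted p = 0.51 with an estimated correlation). Postsynaptic glutamate signalling genes fell in 3 of 20 cases (7 fell and 1 rose over the list alone), Shank3 by −0.60 ± 0.08 and Camk2a by −0.32 ± 0.05 (camera adjusted p = 0.0029, adjusted p = 0.51 with an estimated correlation). Astrocyte markers rose in 3 of 12 cases (5 over the list alone), with Aldoc and the glutamate transporter Slc1a2 both at 0.23 (camera adjusted p = 0.0038, adjusted p = 0.51 with an estimated correlation). In all 774 of 16866 genes were called, 476 higher and 298 lower, and without rescaling 899 higher and 81 lower. Choroid plexus markers had a median of −1.48, and 261 genes were called with their score as a covariate. The count was 363 and 369 without CREB libraries 1 and 4, and 349, 487 and 480 without eGFP libraries 1, 2 and 4.

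In Sleepy cortex CREB gave 11 called genes of 16319, 9 higher and 2 lower. Gpr3, a receptor that raises cAMP, rose from 0.686 ± 0.131 to 1.63 ± 0.288 FPKM (SD, n = 4; log2 1.07 ± 0.15 SE, adjusted p = 0.045) and Rell2 by 0.55 ± 0.06, while Gad1, an enzyme of GABA synthesis, changed by −0.50 ± 0.07. Of 22 CREB-regulated genes none was called over all genes, 9 rose over the list alone, and the median was 0.26. The camera adjusted p was 1.4e-08, and adjusted p = 0.017 with an estimated correlation. Without rescaling 40 genes were higher and 2 lower, and voom called 109. The count was 4, 6, 5 and 3 without CREB libraries 1 to 4 and 3, 7, 5 and 4 without eGFP libraries 1 to 4. In Sleepy hypothalamus Creb1 was the only gene called of 17402, and 1013 had an unadjusted p under 0.05 (870 by chance). There the count was 0 without CREB library 2 or eGFP library 1, 2 or 4, and 2 without CREB library 3 or 4 or eGFP library 3.

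Time of day was compared in wild-type mice with eGFP, ZT12.5 against ZT0.5. Of 14 core clock genes 11 were called in thalamus. Arntl, which encodes BMAL1, fell from 2.27 ± 0.231 to 1.36 ± 0.079 FPKM (SD, n = 4; log2 −0.63 ± 0.08 SE, adjusted p = 0.00091), and Clock changed by −0.35 ± 0.05. Dbp rose from 7.46 ± 0.368 to 18.2 ± 1.70 FPKM (log2 1.33 ± 0.10), Ciart by 1.21 ± 0.11, Per1 by 1.02 ± 0.08, Per2 by 0.95 ± 0.09 and Per3 by 0.92 ± 0.10. In cortex Arntl (−0.86 ± 0.09), Clock (−0.33 ± 0.06), Dbp (1.12 ± 0.11), Ciart (1.32 ± 0.18), Bhlhe41 (0.51 ± 0.08) and Nr1d1 (0.34 ± 0.04) changed, and in hypothalamus Per1 (0.55 ± 0.07), Per2 (0.65 ± 0.10) and Dbp (0.58 ± 0.09). Plin4, of lipid droplets, rose in all 3 regions (1.79 ± 0.21 in cortex, 2.75 ± 0.17 in thalamus, 1.99 ± 0.19 in hypothalamus), as did Hif3a (1.76 ± 0.19, 2.19 ± 0.20 and 2.31 ± 0.25). Fabp7, the brain fatty acid-binding protein, changed by −0.99 ± 0.18, −1.39 ± 0.23 and −1.34 ± 0.18.

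**Figure D5:**
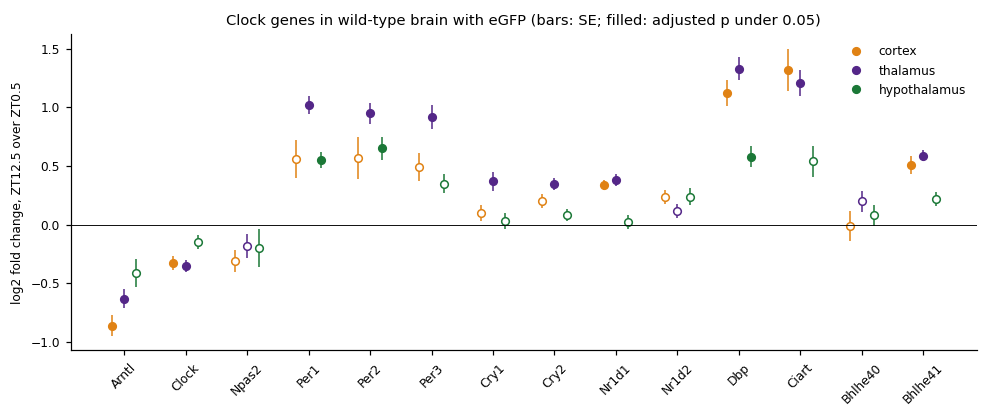
Log2 fold change of the core clock genes (vertical axis), ZT12.5 minus ZT0.5, in wild-type mice with eGFP, by gene and region. Bars are SEs, filled symbols have an adjusted p under 0.05, and in thalamus Dbp stands at 1.33 and Arntl at −0.63.

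In cortex 231 of 16256 genes differed by time, 132 higher and 99 lower at ZT12.5 (66 and 236 without rescaling). Fmo2 rose by 1.43 ± 0.28 SE and Kdr, a receptor of vascular endothelial growth factor, fell by 0.80 ± 0.13. Chaperone genes fell in 6 of 19 cases (11 over the list alone; camera adjusted p = 4.8e-08, adjusted p = 0.41 with an estimated correlation). Endothelial and pericyte genes fell in 4 of 12 cases (5 fell and 1 rose over the list alone; camera adjusted p = 0.00079, adjusted p = 0.21 with an estimated correlation). Clock and clock output genes rose in 4 and fell in 3 of 19 cases (10 and 4 over the list alone; camera adjusted p = 0.024, adjusted p = 0.77 with an estimated correlation). The count was 89, 122 and 97 without ZT12.5 libraries 2, 3 and 4, and 71, 96, 89 and 133 without ZT0.5 libraries 1 to 4. In hypothalamus 33 of 17272 genes differed, 24 higher and 9 lower (25 and 4 without rescaling). The kinase gene Sgk1 rose by 1.84 ± 0.20, Mmp14 changed by −1.13 ± 0.10 and Dynlt1f by −1.17 ± 0.18. Clock and clock output genes rose in 3 of 19 cases there (8 rose and 2 fell over the list alone; camera adjusted p = 0.015, adjusted p = 0.25 with an estimated correlation). The hypothalamus count was 8, 16, 8 and 15 without ZT12.5 libraries 1 to 4 and 20, 5, 20 and 11 without ZT0.5 libraries 1 to 4.

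In thalamus 4353 of 16880 genes differed by time, 2389 higher and 1964 lower (1038 and 1497 without rescaling). Igkc, an immunoglobulin constant region, rose by 2.26 ± 0.41 SE, while Nts, the precursor of neurotensin, changed by −1.28 ± 0.19. Clock and clock output genes rose in 10 and fell in 3 of 19 cases, also over the list alone (camera adjusted p = 0.001, adjusted p = 0.44 with an estimated correlation). Chaperone genes fell in 12 of 19 cases (13 over the list alone; camera adjusted p = 3.3e-07, adjusted p = 0.33 with an estimated correlation). GABA-A receptor subunits fell in 9 and rose in 1 of 12 cases (11 and 1 over the list alone; camera adjusted p = 5.5e-05, adjusted p = 0.33 with an estimated correlation). Mitochondrially encoded mRNAs fell in 7 of 13 cases, also over the list alone (camera adjusted p = 0.00098, adjusted p = 0.66 with an estimated correlation). Ion channels from models of sleep rose in 7 and fell in 2 of 18 cases (9 and 2 over the list alone; camera adjusted p = 0.02, adjusted p = 0.66 with an estimated correlation). Blood cell genes rose in 4 of 5 cases, also over the list alone (camera adjusted p = 0.024, adjusted p = 0.66 with an estimated correlation), and endothelial genes fell in 4 and rose in 1 of 12 (6 and 1 over the list alone; camera adjusted p = 0.049, adjusted p = 0.87 with an estimated correlation). Markers of neighbouring tissue moved with the time as well. Hypothalamus markers fell in 5 of 11 cases (6 over the list alone), with a median of −0.87 (camera adjusted p = 0.011, adjusted p = 0.66 with an estimated correlation). Neuropeptide genes fell in 8 and rose in 1 of 19 cases, also over the list alone (camera adjusted p = 0.01, adjusted p = 0.66 with an estimated correlation), and thalamus markers rose in 5 of 10, also over the list alone (camera adjusted p = 0.02, adjusted p = 0.66 with an estimated correlation).

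Whether an effect differed between genotypes or times was tested by interaction. Creb1 reads, any construct's included, rose more with CREB in Sleepy than wild-type thalamus by 1.22 on the log2 scale (adjusted p = 0.0054). This was the 1 call of limma over the 9 interactions. Voom called 0 there, and 963 genes had an unadjusted p under 0.05. For CREB by genotype limma called 0 genes in cortex and in hypothalamus (712 and 723 unadjusted, and voom 0). For HDAC4CA by genotype it called 0 in each region (775 in cortex, 1016 in thalamus and 732 in hypothalamus unadjusted, and voom 0). The count was 1 in thalamus without Sleepy HDAC4CA library 2, and in hypothalamus without Sleepy eGFP library 2 or 4. For genotype by time it called 0 as well (1062, 1218 and 876 unadjusted, and voom 0, 10 and 0), or 2 in thalamus without Sleepy ZT12.5 library 4. CREB-regulated genes of cortex had a median interaction of 0.19 with 0 of 22 called, also over the list alone (camera adjusted p = 5.4e-05, adjusted p = 0.01 with an estimated correlation). The larger Creb1 rise in Sleepy cortex, not called here, was not allowed for.

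Fold changes were also correlated across genes between comparisons that share no libraries. Genes are not independent replicates, so the value was set against 200 simulations of unchanged groups. For HDAC4CA in wild-type and in Sleepy mice at ZT12.5, Pearson's r was 0.67 in cortex, 0.69 in thalamus and 0.33 in hypothalamus, and 0, 0 and 9 simulations lay as far from 0. Of genes called in both, 392 rose and 300 fell together in cortex (37 and 24.1 for independent lists) and 0 went opposite ways. In thalamus 499 rose, 274 fell (50.4 and 28.4 likewise) and 1 went opposite ways. For CREB in both genotypes r was 0.23, 0.47 and 0.06 (0, 3 and 132 simulations). In thalamus 199 genes rose and 112 fell in both (9.8 and 3.9 for independent lists). For HDAC4CA in Sleepy mice at both times, a pair added after the files had been seen, r was 0.55, 0.41 and 0.24 (0, 3 and 15 simulations). The Sleepy against wild-type difference at ZT12.5 and the HDAC4CA effect in wild-type mice gave r of −0.19 in cortex, −0.26 in thalamus and −0.17 in hypothalamus (1, 23 and 36 simulations). Without the filter on low values r was 0.23, 0.25 and 0.09 for HDAC4CA in both genotypes and 0.17, 0.14 and 0.04 at both times. In cortex and thalamus it was 0.05 and 0.12 for CREB and −0.05 and −0.04 for the Sleepy difference.

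Other pairs shared their control libraries, which alone gives a correlation. Choroid plexus tissue carried along may add to thalamus values of both kinds of pair, which was not tested. For HDAC4CA and CREB in Sleepy thalamus r was 0.48 and the simulated value 0.50, with a covariance of 0.0392 against a simulated 0.0158. The genes called in both were 108 risen, 75 fallen and 44 opposite (29.7, 16.3 and 44.3 for independent lists), and with split controls r was 0.26. In Sleepy cortex and hypothalamus r was 0.33 and 0.48 against a simulated 0.50, and 0.06 and 0.00 with split controls. The covariances were 0.0163 and 0.0171 against 0.0152 and 0.0175. In wild-type thalamus r was 0.23 (0.47 without the filter) against a simulated 0.49, and −0.02 with split controls. The covariance was 0.009 against 0.0116. Wild-type cortex and hypothalamus gave r of 0.36 and 0.35 against 0.51 and 0.50, covariances of 0.0135 and 0.0066 against 0.0115 and 0.011, and −0.02 and −0.10 with split controls. For the Sleepy difference and HDAC4CA in Sleepy mice at ZT12.5, r was −0.44, −0.55 and −0.58 in cortex, thalamus and hypothalamus. The simulated values were −0.50, −0.49 and −0.49. The covariances were −0.0198, −0.032 and −0.0225 against simulated −0.0156, −0.0161 and −0.0167, and r with split controls −0.12, −0.24 and −0.10. At ZT0.5 r was −0.42, −0.42 and −0.49 against −0.50, −0.49 and −0.49, the covariances −0.0177, −0.0201 and −0.015 against −0.014, −0.0149 and −0.0165, and r with split controls −0.10, −0.05 and 0.02.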

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

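The pseudogene test, both gene length tests and the comparison of replicate spread were written before their results were seen, while the splits of libraries and the tests of Ttr levels, of the choroid plexus list at ZT0.5, of the core clock genes and of tissue taken along were chosen only after the result was seen.

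For CREB by genotype in thalamus limma called Creb1, with a log2 difference of 1.22 ± 0.15 SE (adjusted p = 0.0054) from rises of 2.83 ± 0.10 in Sleepy and 1.62 ± 0.09 in wild-type mice, 4 of 4 libraries higher in each. The call was not made with the replicate number as a block or by voom (0 genes each, 939 and 902 at an unadjusted p under 0.05), and 15 of 100 splits called as many genes. Gene lists that passed in an interaction also with an estimated correlation were myelin genes in thalamus for genotype by time (median −0.44, camera adjusted p = 7.7e-21, adjusted p = 0.043 with an estimated correlation; 10 of 12 lower adjusted over the list alone) and CREB-regulated genes in cortex for CREB by genotype (0.19, adjusted p = 5.4e-05, and adjusted p = 0.01 with an estimated correlation). In hypothalamus CREB by genotype gave 0.11 for the LKB1-SIK-CRTC-CREB pathway, which contains Creb1 itself (adjusted p = 0.0013, and adjusted p = 0.021 with an estimated correlation), and 0.15 for genes that respond to sleep loss (adjusted p = 9e-04, and adjusted p = 0.021 with an estimated correlation). The genotypes of the CREB comparisons also differ in control protein and in unit, RPKM or FPKM.

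Single libraries stood far from the 3 others of their group in 42 of 612 sets of a named gene and a group by Dixon's ratio, where chance flags about 1 in 20 groups, or 30.6. In wild-type cortex in RPKM these were, with the range of the others in brackets, C4b 4.91 (4.1 to 4.17), Plk5 0.811 (0.272 to 0.295) and Slc6a5 1.32 (0.343 to 0.466) with HDAC4CA, and Hdac4 3.84 (3.24 to 3.33), Ptprn 63.9 (55.3 to 56.3), Tef 27.1 (24.6 to 24.9) and Slc6a5 0.0592 (0 to 0.00566) with mCherry. Hdac4, Ptprn and Tef stood apart in library 4, of the low kind. In thalamus in RPKM they were Egr4 0.531 (2.3 to 2.31) and Gabra4 10.5 (12.2 to 12.4) with HDAC4CA, Msmo1 7.99 (7.15 to 7.19) and Ndufb9 81.5 (86.4 to 87.2) with mCherry, and Olfr539 0.0451 (0.0825 to 0.0867) with CREB. In hypothalamus in RPKM they were Creb1 3.57 (3.27 to 3.29) and Nrep 4.1 (5.05 to 5.16) with HDAC4CA.

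In wild-type mice with eGFP (FPKM) they were in cortex Clock 6.57 (5.23 to 5.3), Creb1 3.36 (2.75 to 2.8) and Per3 1.18 (1.59 to 1.66) at ZT0.5 and Clock 3.94 (4.18 to 4.22) and Nr1d2 11.3 (9.94 to 10.1) at ZT12.5. In thalamus at ZT12.5 Bhlhe40 7.84 (9.69 to 9.87), Nr1d2 13.8 (15.4 to 15.7) and Sik3 12.9 (13.8 to 13.9) were all from library 2. In hypothalamus they were Cry2 7.44 (8.26 to 8.27), Sik3 11.8 (13.6 to 13.6), Hif3a 0.0489 (0.18 to 0.189) and Per2 2.63 (2.01 to 2.08) at ZT0.5 and Npas2 0.773 (1.13 to 1.19) at ZT12.5.

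In Sleepy mice (FPKM) they were in cortex Blnk 0.385 (0.425 to 0.431) with eGFP at ZT0.5, Plk5 1.35 (0.273 to 0.291), Nrn1 62.2 (48.8 to 50.3) and Hsph1 23.5 (26.3 to 26.5) with HDAC4CA at ZT0.5, and Gpr3 2.05 (1.44 to 1.51) with CREB. In thalamus with eGFP they were Nfam1 0.772 (1.29 to 1.38), Peg10 4.08 (5.31 to 5.54), Cyp51 9.01 (8.11 to 8.17) and Vamp2 95.7 (89.4 to 90.5) at ZT0.5 and Dnajb1 6.18 (7.35 to 7.38) and Shank1 45.8 (51.9 to 53.1) at ZT12.5. With a transgene in thalamus they were Cck 14.1 (8.72 to 9.48) with HDAC4CA at ZT0.5, Hbb-bs 35.5 (16 to 18.9) with HDAC4CA at ZT12.5 and Sik1 4.85 (4.54 to 4.59) with CREB, and in hypothalamus Creb1 5.73 (6.65 to 6.71) with CREB.

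Choroid plexus genes fell in Sleepy thalamus with HDAC4CA at ZT12.5 (median log2 −4.14, Ttr 8.27 ± 2.66 against 961 ± 445 FPKM). A difference in the choroid plexus tissue carried along in dissection is a candidate explanation: 2 of 20 thalamus libraries without HDAC4CA in FPKM lay at or under 11.7 FPKM of Ttr, the highest value of the HDAC4CA group, with a lowest of 10.1 and a highest of 1583. An effect of HDAC4CA cannot be told apart from it: at ZT0.5 the median was 0.15, but the libraries varied so widely that the 95% interval of the mean difference over the 11 markers ran from −3.18 to 3.58. An effect limited to ZT12.5 stays open as well. Wild-type thalamus with HDAC4CA gave a median of −1.93 with 0 of 11 genes called by limma (camera adjusted p = 0.02, adjusted p = 0.97 with an estimated correlation).

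Gapdh and ribosomal protein genes were low in replicate 4 of each wild-type cortex group in RPKM, by a log2 difference of −3.17 for Gapdh and a median of −1.90 over 80 ribosomal protein genes, and thalamus and hypothalamus libraries in RPKM had Gapdh at 4.79 to 7.18. Reads shared with pseudogenes, counted in another way, may have a part: 172 genes with a named pseudogene lay −0.27 from 13566 others (bootstrap −0.33 to −0.19 in 1000 draws), short of the −0.5 set for a cause. Gene length gave a Spearman rho of 0.12 over 13738 genes and cannot be told apart from it, as a weak trend neither reaches the 0.3 set for a cause nor excludes one. No biological explanation was tested.

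Time of day called 4353 genes in thalamus against 231 in cortex and 33 in hypothalamus. A smaller spread of thalamus libraries is argued against. The lower other median SE over that of thalamus was 1.00 (0.11, 0.10 and 0.10 in cortex, thalamus and hypothalamus). The median size of the fold changes was 0.12, 0.18 and 0.09. Core clock genes were called in cortex and hypothalamus too, so the 11 of 14 in thalamus do not tell why it called more. A biological effect of time is a hypothesis. A gene length trend and tissue taken along in dissection cannot be told apart from it. For gene length rho was −0.19 in thalamus, −0.15 in cortex and −0.01 in hypothalamus. For tissue, rho with hypothalamus over thalamus in Sleepy eGFP libraries (16880 genes) was −0.17 at ZT0.5 and −0.48 at ZT12.5. The latter passes the bound set above for gene length, but the time of day it shares was not separated.

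Other splits of the same 8 libraries, 35 in all, were refitted. In some cases only the real split (1 of 35) reached its count, a share of 0.029, which is the lowest that 35 splits can give. The splits were chosen after the counts were seen, with no allowance for the number of comparisons, so chance is not excluded. These cases follow, with the highest other split in brackets. HDAC4CA in wild type gave 1260 (278) and 23 (6) genes in thalamus and hypothalamus, and CREB in wild type 560 (2) in thalamus. Sleepy against wild-type thalamus at ZT0.5 gave 6 (1). HDAC4CA in Sleepy mice gave 704 (2) and 1436 (102) in cortex and thalamus at ZT0.5 and 1779 (1), 2020 (1) and 12 (1) in cortex, thalamus and hypothalamus at ZT12.5. CREB in Sleepy mice gave 11 (1) and 774 (1) in cortex and thalamus, and time 231 (1), 4353 (1) and 33 (2) in cortex, thalamus and hypothalamus.

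In wild-type cortex the numbers pair the libraries, and the real split parts all 4 pairs. The highest other of the 8 splits that do so gave 0 genes by limma for either transgene, against 1087 for HDAC4CA and 8 for CREB, and 0 with the replicate block as well, against 966 and 1. These 8 splits are too few for a share under 0.05. The others of the 35 put at least 1 pair, in some the low kind, on 1 side, and gave at most 0 and 1.

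The share was above 0.05 for HDAC4CA at ZT0.5 in Sleepy hypothalamus, 3 (116), and for CREB there, 1 (1), each reached by 2 of 35 splits. The split with 116 genes put HDAC4CA libraries 1 and 3 with eGFP libraries 3 and 4 against the rest, and what sets it apart was not tested. Comparisons in which limma called 0 genes say nothing here, as all 35 splits reach that count. These included CREB in wild-type hypothalamus (highest other split 1, 655 genes at an unadjusted p under 0.05). Others were Sleepy against wild type in cortex and hypothalamus at ZT0.5 (2 and 114, with 966 and 769 unadjusted). At ZT12.5 they were cortex, thalamus and hypothalamus (1, 6 and 2, with 1083, 1337 and 1455 unadjusted). The split with 114 genes put Sleepy libraries 1 and 2 with wild-type libraries 1 and 4, and what sets it apart was not tested either. For the interactions 100 splits were drawn, and the share was under 0.05 for none: CREB by genotype in thalamus called 1 gene (highest other split 2), reached by 15 of 100. The other interactions called 0 genes by limma, reached by 100 of 100. The highest other splits in cortex, thalamus and hypothalamus were 3, 1 and 1 for genotype by time (1062, 1218 and 876 unadjusted). They were 1, 4 and 4 for HDAC4CA by genotype (775, 1016 and 732 unadjusted). CREB by genotype had 1 and 2 in cortex and hypothalamus (712 and 723 unadjusted).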

How the results depend on the processing

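Median-of-ratios scaling, no filter on low values, a replicate block, each library left out, and an estimated correlation and fry for gene lists were chosen before the data were examined, while the tests without rescaling, with a pseudocount of 1, with voom on recovered reads, with a term for library kind, without cortex libraries of the low kind and with a choroid plexus score were chosen only after the result was seen. Main values stand in brackets. DESeq2 and edgeR tests were not run, as the values are RPKM and FPKM. Depth limits what can be said of genes with a mean under 10 recovered reads. With 4 libraries per group, 29.9% of genes changed 1.5-fold were called in simulated data of HDAC4CA in wild-type cortex, 32.8% in those of Sleepy against wild-type thalamus at ZT12.5 and 61.2% in those of CREB in wild-type hypothalamus. Where a count moved, the cause was not tested.

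Without the filter more genes were tested, 31128 against 15891 for HDAC4CA in wild-type cortex, and the larger counts dropped, while many counts near 0 rose. In cortex the counts were 477 (1087) for HDAC4CA in wild type, 5 (8) for CREB in wild type, 9 (0) and 3 (0) for Sleepy against wild type at ZT0.5 and ZT12.5, 224 (704) and 1089 (1779) for HDAC4CA in Sleepy mice at ZT0.5 and ZT12.5, and 64 (231) for time. The cortex interactions of genotype by time, HDAC4CA by genotype and CREB by genotype gave 1 (0), 1 (0) and 3 (0). Thalamus gave 687 (1260) and 240 (560) for HDAC4CA and CREB in wild type, 2 (0) for Sleepy against wild type at ZT12.5, 937 (1436) and 1163 (2020) for HDAC4CA in Sleepy mice, and 333 (774) for CREB in Sleepy mice. Its interactions gave 3 (0), 4 (0) and 5 (1). Hypothalamus gave 11 (23) and 1 (0) for HDAC4CA and CREB in wild type, 4 (0) and 7 (0) for Sleepy against wild type, 5 (3) for HDAC4CA at ZT0.5 and 2 (1) for CREB in Sleepy mice, 15 (33) for time and 3 (0) for HDAC4CA by genotype.

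Without rescaling cortex gave 582 (1087) and 5 (8) for HDAC4CA and CREB in wild type, 404 (704) and 1081 (1779) for HDAC4CA in Sleepy mice at ZT0.5 and ZT12.5, and 42 (11) for CREB in Sleepy mice. Thalamus gave 267 (560) for CREB in wild type, 1081 (2020) for HDAC4CA in Sleepy mice at ZT12.5 and 2535 (4353) for time. Hypothalamus gave 5 (12) for HDAC4CA at ZT12.5 and 2 (1) for CREB in Sleepy mice, and 1 (0) for CREB by genotype. A pseudocount of 1 gave 3 (8) for CREB in wild-type cortex and 1 (0) for HDAC4CA by genotype in thalamus. Without the low kind of library, HDAC4CA and CREB in wild-type cortex gave 512 (1087) and 5 (8), and with a term for library kind 1414 (1087) and 12 (8). The choroid plexus score left 0 (2020) genes called by limma for HDAC4CA in Sleepy thalamus at ZT12.5, with 1121 at an unadjusted p under 0.05, and 261 (774) for CREB.

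With voom on recovered reads cortex gave 14 (8) for CREB in wild type, 3 (0) for Sleepy against wild type at either time, 1258 (704) for HDAC4CA at ZT0.5 and 109 (11) for CREB in Sleepy mice, and 802 (231) for time. Thalamus gave 47 (6) and 2 (0) for Sleepy against wild type at ZT0.5 and ZT12.5, 1164 (774) for CREB in Sleepy mice, 10 (0) for genotype by time and 0 (1) for CREB by genotype, where 902 genes had an unadjusted p under 0.05. Hypothalamus gave 86 (23) and 1 (0) for HDAC4CA and CREB in wild type, 3 (0) for Sleepy against wild type at ZT12.5, 26 (3) and 73 (12) for HDAC4CA in Sleepy mice at ZT0.5 and ZT12.5, and 174 (33) for time.

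In wild-type cortex with HDAC4CA or CREB all 4 same-number pairs correlated above 0.1. There the block gave 966 genes for HDAC4CA, 816 of them among the 1087, and 1 of the 8 for CREB. In Sleepy against wild-type hypothalamus at ZT12.5 all 4 libraries correlated best with their own number, as a hint from the data, not the design. With the replicate number as a block, cortex gave 1 (8) for CREB in wild type, 424 (704) for HDAC4CA at ZT0.5 and 0 (11) for CREB in Sleepy mice, and 112 (231) for time. Thalamus gave 200 (560) for CREB in wild type, 0 (6) for Sleepy against wild type at ZT0.5, 873 (1436) for HDAC4CA in Sleepy mice at ZT0.5 and 0 (1) for CREB by genotype. Hypothalamus gave 14 (23) for HDAC4CA in wild type, 0 (12) for HDAC4CA at ZT12.5 and 0 (1) for CREB in Sleepy mice, and 16 (33) for time. Where limma with the block called 0 genes, the numbers at an unadjusted p under 0.05 were 1446 for CREB in Sleepy cortex, 915 for Sleepy against wild-type thalamus, 939 for the thalamus interaction, and 1561 and 883 for HDAC4CA and CREB in Sleepy hypothalamus. The other counts with the block stayed within 1.5 times, and of 333 named genes by comparison 65 lost their call.

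Each library left out in turn gave ranges in counts. HDAC4CA in wild type ranged over 505 to 1970 (1087) in cortex, 734 to 1237 (1260) in thalamus and 8 to 193 (23) in hypothalamus, and CREB in wild type over 1 to 3 (8) in cortex and 192 to 592 (560) in thalamus. Sleepy against wild-type thalamus ranged over 0 to 7 (6) at ZT0.5 and 0 to 1 (0) at ZT12.5. HDAC4CA in Sleepy mice ranged over 311 to 819 (704) in cortex and 938 to 1293 (1436) in thalamus at ZT0.5, and 1287 to 1801 (2020) in thalamus and 2 to 5 (12) in hypothalamus at ZT12.5. CREB in Sleepy mice gave 3 to 7 (11) in cortex, 349 to 729 (774) in thalamus and 0 to 2 (1) in hypothalamus. Time gave 71 to 159 (231) in cortex and 5 to 20 (33) in hypothalamus. Genotype by time gave 0 to 2 (0) in thalamus, and HDAC4CA by genotype 0 to 1 (0) in thalamus and in hypothalamus.

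Correlations of fold changes between comparisons moved without the filter. HDAC4CA with CREB gave 0.47 (0.23) in wild-type thalamus and 0.49 (0.33) in Sleepy cortex, and Sleepy with HDAC4CA in Sleepy cortex at ZT0.5 gave −0.54 (−0.42). HDAC4CA in wild type with HDAC4CA in Sleepy mice gave 0.23 (0.67), 0.25 (0.69) and 0.09 (0.33) in cortex, thalamus and hypothalamus, and CREB likewise 0.05 (0.23) and 0.12 (0.47) in cortex and thalamus. Sleepy at ZT12.5 with HDAC4CA in wild type gave −0.05 (−0.19) in cortex and −0.04 (−0.26) in thalamus, and HDAC4CA at ZT0.5 with ZT12.5 gave 0.17 (0.55), 0.14 (0.41) and 0.04 (0.24) in cortex, thalamus and hypothalamus. A pseudocount of 1 gave 0.30 (0.23) for CREB in cortex of both genotypes. With 1 replicate number left out of every group, HDAC4CA in both genotypes ranged over 0.57 to 0.62 (0.67) in cortex and 0.51 to 0.71 (0.69) in thalamus, and CREB in both over 0.13 to 0.22 (0.23), 0.23 to 0.54 (0.47) and 0.03 to 0.25 (0.06) in cortex, thalamus and hypothalamus. Sleepy with HDAC4CA in Sleepy cortex at ZT12.5 ranged over −0.48 to −0.34 (−0.44). Sleepy at ZT12.5 with HDAC4CA in wild type ranged over −0.20 to −0.05 (−0.19) in cortex and −0.27 to 0.01 (−0.17) in hypothalamus. HDAC4CA at both times ranged over 0.43 to 0.54 (0.55), 0.18 to 0.51 (0.41) and 0.07 to 0.22 (0.24) in cortex, thalamus and hypothalamus. Of 1229 tests of gene lists camera called 288 at the preset correlation of 0.01, 7 with an estimated correlation, and fry called 87.

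Of 4864 values of named genes under the alternatives, 3961 kept direction and side of the threshold, 831 kept direction without the call, 12 gained it and 60 changed sign. Without the values of a library left out these were 1884, 289, 10 and 17 of 2200. Over all alternatives, libraries left out included, 170 of 333 genes by comparison never lost call or sign. With the choroid plexus score in Sleepy thalamus with HDAC4CA at ZT12.5 the log2 differences of Gal, Egr3, Syn1 and Pdia4 were −3.34 (2.39), −1.92 (2.02), −0.11 (0.26) and 0.53 (−0.39), none of them called. The other changes of sign were in differences near 0. Without rescaling Creb1 gave −0.04 (0.01) and −0.03 (0.02) in Sleepy against wild-type thalamus at ZT0.5 and ZT12.5, −0.01 (0.02) in hypothalamus at ZT12.5, and with HDAC4CA in Sleepy mice −0.01 (0.06) in thalamus and 0.03 (−0.03) in hypothalamus at ZT0.5, and −0.02 (0.01) and −0.04 (0.00) at ZT12.5. Hdac4 gave −0.02 (0.01) and −0.03 (0.01) in Sleepy against wild-type cortex and thalamus at ZT0.5 and −0.02 (0.04) by time in thalamus, and Sik3 −0.01 (0.03) and −0.04 (0.00) with HDAC4CA in wild-type and Sleepy hypothalamus at ZT12.5. Median-of-ratios scaling gave 0.00 for Creb1 in the latter.

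With a library left out, Sleepy against wild type ranged for Creb1 over −0.04 to 0.04 in thalamus at ZT0.5 and −0.01 to 0.08, −0.02 to 0.07 and −0.04 to 0.04 in cortex, thalamus and hypothalamus at ZT12.5. Hdac4 ranged there over −0.03 to 0.04, −0.01 to 0.03 and −0.03 to 0.02 in cortex, thalamus and hypothalamus at ZT0.5 and −0.04 to 0.01 in hypothalamus at ZT12.5. With HDAC4CA in Sleepy mice at ZT12.5 Creb1 ranged over −0.09 to 0.01, −0.01 to 0.03 and −0.02 to 0.03 in the 3 regions, and Sik3 over −0.03 to 0.04 in hypothalamus and, at ZT0.5, −0.05 to 0.01 in thalamus. With CREB, Hdac4 in Sleepy hypothalamus ranged over −0.02 to 0.03 and Sik3 in wild-type hypothalamus over −0.04 to 0.00. By time Hdac4 and Bhlhe40 in cortex ranged over −0.05 to 0.01 and −0.13 to 0.09, and Cry1 and Nr1d1 in hypothalamus over 0.00 to 0.08 and −0.02 to 0.06.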

Other observations

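The gene lists were fixed before the data were examined, while the lists and genes described here were chosen after their values were seen. In Sleepy against wild-type cortex at ZT0.5, microglia markers had a median log2 difference of −0.31 with 7 of 13 lower adjusted over the list alone (camera adjusted p = 1.6e-07, adjusted p = 0.28 with an estimated correlation).

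In wild-type hypothalamus with HDAC4CA, 11 of 22 CREB-regulated genes were higher adjusted over the list alone, with a median of 0.26 (camera adjusted p = 1.8e-10, adjusted p = 0.44 with an estimated correlation), and immediate early genes had a median of 0.49 with 0 of 20 called (camera adjusted p = 3.3e-08, adjusted p = 0.63 with an estimated correlation). HDAC4CA library 1 stood low there, with Egr1 at 1.76 against 25.4 to 27.1 RPKM in the other 3, Fos at 1.56 against 5.81 to 8.25 and Arc at 1.65 against 4.37 to 15.3. Number 1 was low with HDAC4CA also in wild-type cortex (Fos 1.55 against 12.6 to 33.9, Npas4 0.354 against 5.25 to 67.9, Nptx2 7.88 against 33.5 to 146) and thalamus (Egr1 4.57 against 15.4 to 33.7). In Sleepy mice with HDAC4CA at ZT0.5 number 3 was high, with Npas4 at 14.6 against 0.327 to 1.33 FPKM in cortex and Egr1 at 18.5 against 4.09 to 4.91 in thalamus and 21.8 against 2.44 to 6.05 in hypothalamus. The other genes called in wild-type cortex with CREB were Cdk15 (1.24), Cenpa (1.1), Mustn1 (1.16), Gm12744 (−0.37) and Hist1h2bb (−3.80), and with the replicate number as a block Creb1 alone was called there. Reactive astrocyte genes had a median of 0.47 in that comparison with 0 of 11 called (camera adjusted p = 2.4e-06, adjusted p = 0.29 with an estimated correlation), astrocyte and microglia markers of 0.09 and 0.16 with 0 called (camera adjusted p = 1.8e-05 and 0.00017, and adjusted p = 0.24 and 0.42 with an estimated correlation), and CREB-regulated genes of 0.06 with 6 of 22 higher adjusted over the list alone (camera adjusted p = 0.0015, adjusted p = 0.16 with an estimated correlation).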
